A study of Mus musculus with 15 samples.

How the data were processed

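RNA of lung tissue from C57BL/J mice was sequenced in 15 libraries: control (n = 4), DMSO (n = 4), silica (n = 3) and silica_DMSO (n = 4), with groups taken from the labels. The deposited count table holds expected counts, per the file headers a count per gene and library, of which 7.52% to 10.0% per library are not whole numbers. The deposited TPM table holds TPM made by the authors, and each library's column sums to the same total. Both tables also hold the authors' means per group of the expected counts and of the TPM, 8 columns not used here, and a gene length in bases, an other value given by the authors. The submitters' processing notes name Bowtie 0.12.2 and genome build mm8, which could not be checked against these tables, and the program that estimated the counts is not given in the sources used here. The extraction notes of the labels describe retinas while the tissue field says lung. Not all genes looked up for this are reported here. Of the gene identifiers, 52029 (91.3%) were in the GENCODE M21 name table.

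Expected counts were rounded to whole counts, which changed a library's total by at most 53.9 counts. Totals ran from 17434649 to 20829960 counts. Genes were filtered with edgeR's filterByExpr by group (smallest count 10, smallest total 15), which left 17879 of 57010 genes, and libraries were scaled by TMM. Data were processed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and the package data.table (version 1.17.8), and figures drawn in Python 3.11.15 with matplotlib 3.10.9.

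Changes per gene were tested with edgeR's quasi-likelihood F test (robust) in a fit of 4 group means, with contrasts for silica against control, silica_DMSO against silica, DMSO against control, silica_DMSO against DMSO, silica_DMSO against control, and the interaction of silica and DMSO. P-values were adjusted by Benjamini and Hochberg, and a gene is called at an adjusted p under 0.05. They measure the spread between libraries. Fold changes are on the log2 scale with their standard error (SE). Normalised CPM are scaled by TMM, and the values per library given as CPM are of the library total.

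Gene lists of cell types and pathways, 47 in all and fixed in advance, were tested with limma camera on log2 CPM (prior count 2) at a preset correlation between genes of 0.01, adjusted over the 46 lists with at least 5 genes tested. The same test with a correlation estimated per list, and limma's fry, were run beside it. The mean change given for a list is the mean of edgeR's log2 fold changes of its genes. Camera tests log2 CPM instead, so its p-value belongs to a difference that can deviate from that mean in size or sign. Members of a list were also adjusted over the list alone.

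Genes named were set by a rule. Per comparison these were up to 8 genes with the highest and up to 8 with the lowest fold change among called genes with a mean of at least 1 CPM and no overlap of the groups' libraries, leaving out predicted genes, pseudogenes and variable segments of immunoglobulin and T cell receptor genes. Added were the 3 genes of smallest p in each list that passed, 12 genes of fibrosis and inflammation for silica against control and silica_DMSO against silica, and the 3 genes of smallest p where none was called. Genes of larger p beyond about 30 were left out. Genes named from the fit of the 7 silica and control libraries were chosen after their values were seen.

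The comparisons, lists, rule for genes and most alternatives were chosen before the data were examined. These alternatives were DESeq2 size factors or upper-quartile factors in edgeR, DESeq2's own test, limma-voom with quality weights, limma-trend on log2 TPM with a pseudocount of 1 or 0.1, no filter or one of 1 CPM in 3 libraries, a fold minimum, an adjusted p under 0.1, the label's number as a replicate block, a fit of only the groups compared, and leaving out each library in turn. Chosen after seeing the data were fits without the 3 libraries with thymus RNA, with a per-library offset for gene length, without control 1, DMSO 4 or silica_DMSO 5 on top of those 3, and leaving out each of the 7 silica and control libraries in their own fit. The tests were tried on simulated data with 50 changed genes per fold.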

Results

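Lung RNA from C57BL/J mice was sequenced in 15 libraries of 4 groups. The control group (n = 4) received saline, the DMSO group (n = 4) received dimethyl sulfoxide, the silica group (n = 3) received a suspension of silica particles as nasal drops, and the silica_DMSO group (n = 4) received silica and, on the second day, DMSO. Lungs were collected at day 30. Estimated counts summed to between 17434649 and 20829960 per library, and 17879 of the 57010 genes in the count table passed the filter on low counts. The replicate numbers come from the labels, which do not state whether each library is a separate animal, so the p-values per gene measure the spread between these libraries. Camera p-values set a list against other genes at a preset correlation and do not measure that spread alone. Regrouped at the same group sizes, the 15 libraries gave up to 21 lists for silica against control, where the real groups gave 23. For DMSO against control these were 25 and 21, and for silica_DMSO against DMSO 31 and 25. Spread between libraries of a group was wide, with a biological coefficient of variation of 0.666.

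Thymus genes separated 3 libraries from the rest. In the libraries labelled DMSO 7, silica_DMSO 4 and silica_DMSO 6, Rag1, the recombinase that cuts antigen receptor genes in developing lymphocytes, reached 3876, 2743 and 2541 CPM, while the other 12 libraries held at most 0.224 CPM. Dntt, the template-free DNA polymerase of immature lymphocytes, was at 1312, 1420 and 2068 CPM in the 3 libraries and at most at 0.433 CPM elsewhere. Foxn1, the master regulator of thymic epithelium, lay between 9.17 and 27.0 CPM in the 3 libraries and had 0 counts in the other 12. The median alveolar type 2 gene in these libraries stood at 23.2%, 3.65% and 0.701% of its mean in the other 12, and the median endothelial gene at 34.4%, 4.14% and 2.37%. The first principal component, with 48.7% of the variance, parted these 3 libraries from the other 12. Because they sit in the DMSO and silica_DMSO groups, gene counts of every comparison with those groups, and most list means, are given with and without them, the second chosen after the data were seen.

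**Figure D1:**
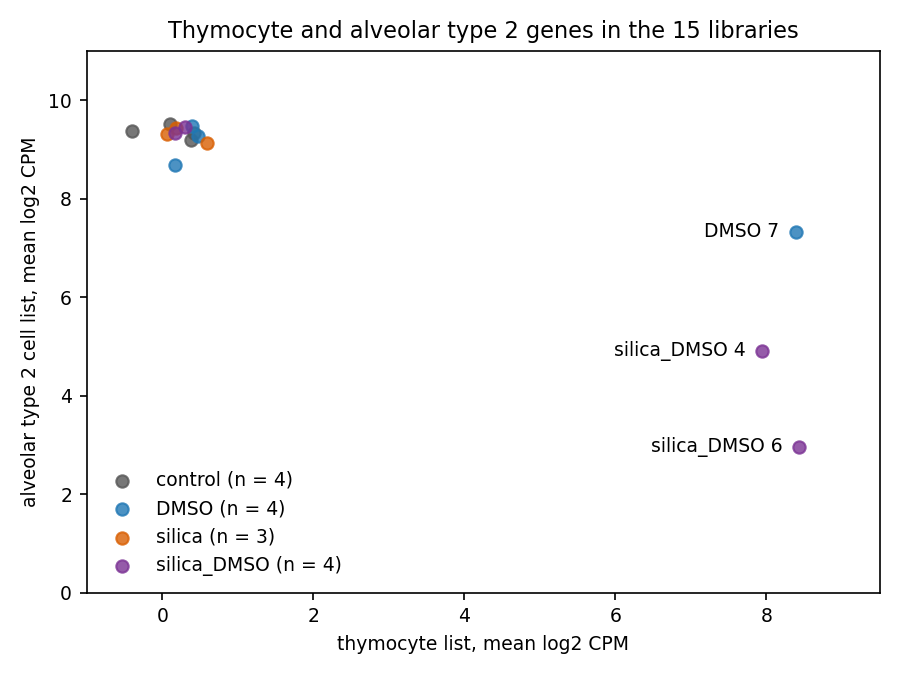
Mean log2 CPM of the thymocyte gene list (horizontal axis) and of the alveolar type 2 cell list (vertical axis) in each of the 15 libraries, with points coloured by group. The libraries labelled DMSO 7, silica_DMSO 4 and silica_DMSO 6 lie at thymocyte values of 7.94 or more, and the other 12 libraries at 0.597 or less.

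Gene length set libraries apart within every group. In control 1, DMSO 1, DMSO 4, silica 7 and silica_DMSO 5 the deviation of gene levels from the median of all libraries correlated negatively with gene length across genes, with r from -0.584 to -0.174. In the other 7 libraries without thymus RNA r lay from 0.0602 to 0.452, and genes are not independent replicates. Genes over 3000 bases took 11.5% to 24.2% of counts in the 5 libraries and 34.0% to 44.9% in the other 7. Scgb1a1, the secretoglobin of airway club cells, took 8.83% to 14.2% of counts in the 5 and 0.927% to 5.31% in the other 7.

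**Figure D2:**
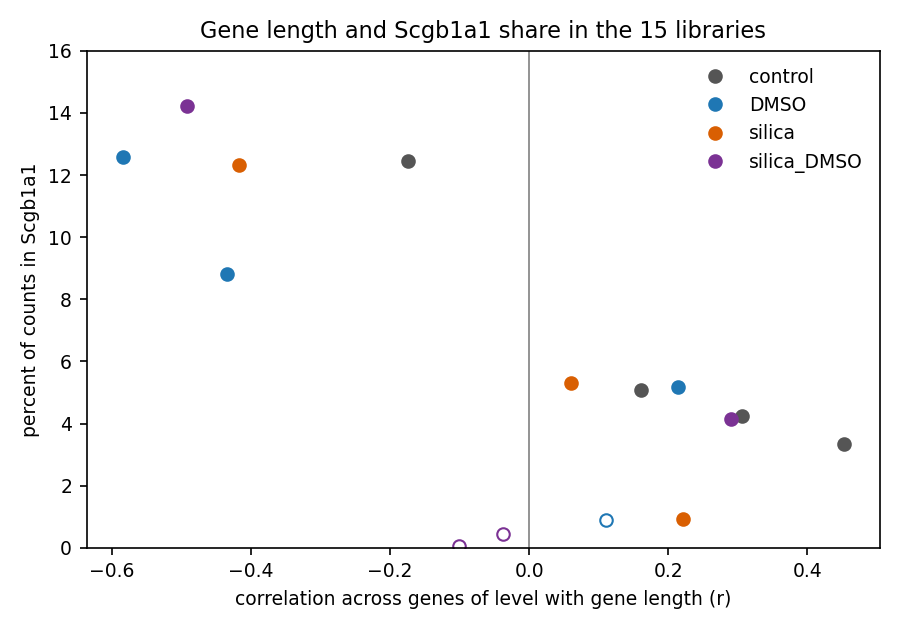
Correlation across genes of the deviation in level with gene length (horizontal axis) against the percent of counts in Scgb1a1 (vertical axis) for each library, with open points for the 3 libraries with thymus RNA. The 5 libraries with negative correlations among the filled points hold at least 8.83% of their counts in Scgb1a1, and the other 7 at most 5.31%.

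The comparison of silica with control gives the effect of silica without DMSO. Silica lungs held more RNA of macrophage, chemokine, IL-1 and NF-kB genes than control lungs, and less RNA of mesothelial genes. The 20 genes of lipid-handling and Spp1-expressing macrophages rose by a mean of 1.90 on the log2 scale, and 19 of them were higher (limma camera adjusted p = 1.65e-21; adjusted p = 0.0433 with an estimated correlation). The 15 inflammasome and IL-1 genes rose by 1.12 (adjusted p = 7.33e-09; adjusted p = 0.0433 with an estimated correlation), and the 18 NF-kB targets rose by 0.80 (adjusted p = 6.82e-08; adjusted p = 0.00778 with an estimated correlation). With only the 7 silica and control libraries, camera with an estimated correlation did not call the NF-kB targets (adjusted p = 0.0549). It called monocyte and interstitial macrophage genes there (adjusted p = 0.0412). Cytokines and chemokines rose by 1.98 over 28 genes (adjusted p = 1.21e-20; adjusted p = 0.0669 with an estimated correlation). The 9 mesothelial genes fell by 2.49 (adjusted p = 2.31e-11; adjusted p = 0.0847 with an estimated correlation).

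Single genes passed the test when the silica and control libraries were fitted alone. With the 7 libraries in the fit, edgeR's quasi-likelihood test called 41 of 16467 genes, 40 higher and 1 lower in silica. For each of the 40, every silica library lay above every control, which choosing genes by the test nearly ensures. Mmp12 (ENSMUSG00000049723), an elastase of macrophages, rose by 4.83 ± 0.29 (SE, adjusted p = 0.00117), from 8.35 ± 2.04 to 239 ± 32.9 normalised CPM (SD, n = 4 and 3). Il1rn (ENSMUSG00000026981), the antagonist of the IL-1 receptor, rose by 3.12 ± 0.28 (adjusted p = 0.00716), from 8.15 ± 2.20 to 71.1 ± 7.64 normalised CPM. The chemokine genes Cxcl9, Cxcl10 and Ccl2, which recruit T cells and monocytes, rose by 4.32, 3.29 and 3.15 (adjusted p = 0.0114, 0.0178 and 0.0484). Gpnmb and Cd68, a glycoprotein and a lysosomal marker of phagocytes, rose by 4.58 and 2.43 (adjusted p = 0.0462 and 0.0476), and the complement gene C1qc by 1.89 (adjusted p = 0.0114). Saa3, an acute-phase protein, rose by 4.75 (adjusted p = 0.0468) and Clca1, a secreted product of goblet cells, by 4.31 (adjusted p = 0.0125). A rise in these genes was not limited to silica. In DMSO 4, without silica, the 40 genes lay a median of 2.85 above the controls, against 2.88 in the silica libraries and -0.068 in DMSO 6. Cxcl9, Clca1 and C1qc stood 5.37, 7.68 and 2.94 above the controls in DMSO 4, but Mmp12 and Il1rn only 0.71 and 1.29. The 40 genes were also short (median 1497 bases, against 2649 over tested genes).

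Further genes among the 41 were chosen after their values were seen. The lectin receptor genes Clec7a, Clec4n and Clec4d rose by 2.62, 3.01 and 3.60, and Trem2, a lipid-sensing receptor of macrophages, by 2.62 (adjusted p between 0.00973 and 0.0462). Ctsk, a collagen-degrading cathepsin, rose by 3.09 (adjusted p = 0.00973), Lcn2, an iron-sequestering lipocalin, by 2.79 (adjusted p = 0.0149) and Acod1, which makes itaconate, by 6.31 (adjusted p = 0.0476). Slc39a2, a zinc transporter, rose by 3.26 (adjusted p = 0.00973). The lower gene was Colq, the collagen tail of acetylcholinesterase, which fell by 1.63 (adjusted p = 0.0492), from 18.5 ± 1.13 to 5.96 ± 1.10 normalised CPM (SD). By list, 19 of the 41 were in at least 1, and 6 belonged to lipid-handling and Spp1 macrophages, 5 to cytokines and chemokines, 2 to monocytes and interstitial macrophages and 2 to goblet cells and mucus.

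**Figure D3:**
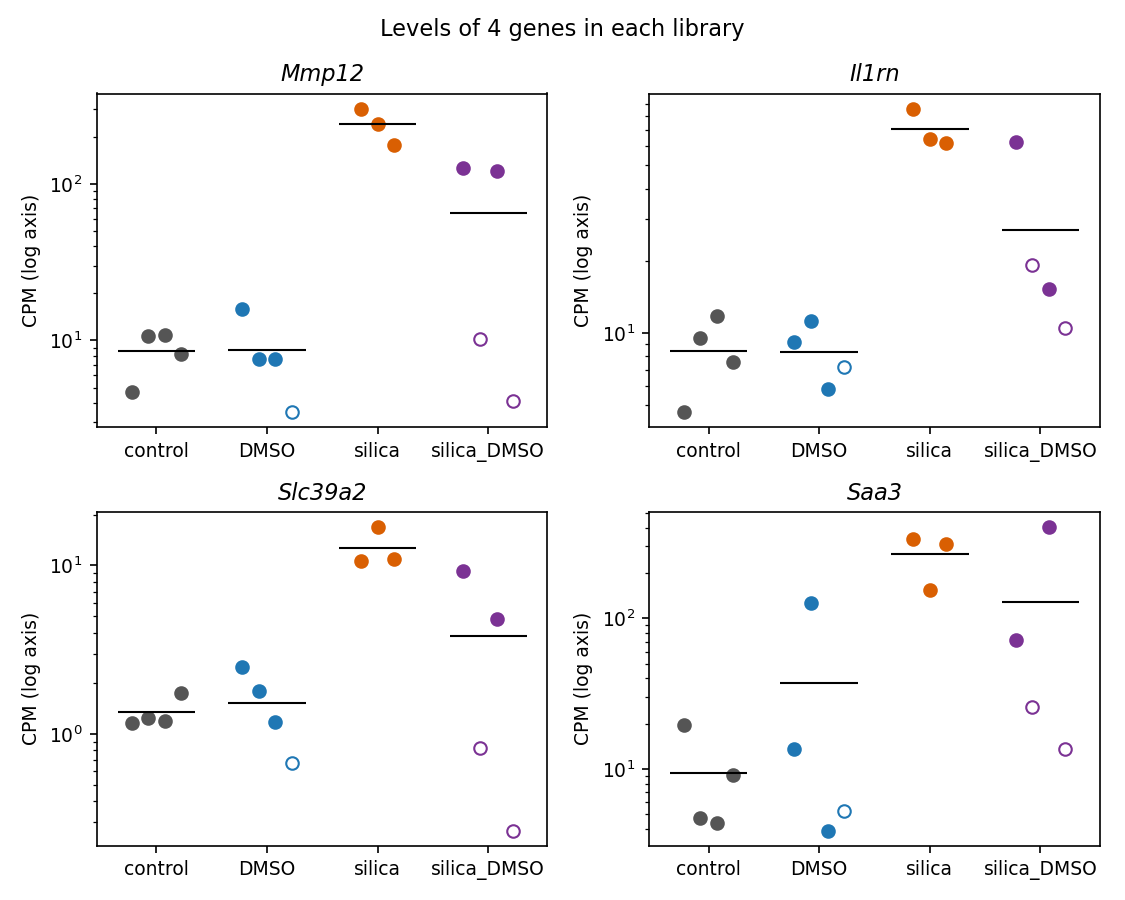
CPM of the library total for Mmp12, Il1rn, Slc39a2 and Saa3 (vertical log axes) in each library by group (horizontal axes), with a bar at the group mean and open points for the 3 libraries with thymus RNA. Mmp12 lies between 178 and 303 CPM in the 3 silica libraries, at 127 and 121 CPM in silica_DMSO 2 and 5, and at no more than 15.9 CPM in every control and DMSO library.

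In the fit of all 15 libraries, edgeR called 0 genes between silica and control, with 522 at an unadjusted p under 0.05, while DESeq2 called 39 and limma-voom with quality weights 1470. The smallest edgeR adjusted p, 0.318, belonged to Cxcl10, Lhfpl2 and Il1rn, which DESeq2 called (adjusted p = 0.000370, 0.000186 and 0.000186). Without the 3 libraries with thymus RNA the count was 2, Mmp12 (4.80 ± 0.42, adjusted p = 0.00235) and Slc39a2 (3.24 ± 0.40, adjusted p = 0.0370). The 7-library count was largest with every library in: it fell to 24, 3, 8 and 1 without control 1, 2, 4 or 7, and to 37, 21 and 28 without silica 1, 2 or 7, with Mmp12 called each time. Of the 41 genes, DESeq2 on all libraries also called 12.

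Other gene groups parted silica from control in the 15-library fit, in which edgeR called no list member over all genes tested. The 16 monocyte and interstitial macrophage genes rose by 0.96 (adjusted p = 4.36e-07; adjusted p = 0.0847 with an estimated correlation). The 14 neutrophil genes rose by 1.39 (adjusted p = 2.11e-06; adjusted p = 0.197 with an estimated correlation), and the 24 interferon response genes by 0.67 (adjusted p = 7.33e-09; adjusted p = 0.197 with an estimated correlation). The 12 goblet and mucus genes rose by 1.83 (adjusted p = 7.54e-07; adjusted p = 0.224 with an estimated correlation). The 21 cell cycle genes rose by 1.26 (adjusted p = 1.71e-07; adjusted p = 0.496 with an estimated correlation). The 13 cardiac muscle genes fell by 1.22 (adjusted p = 6.23e-05; adjusted p = 0.460 with an estimated correlation). The 17 endothelial genes fell by 0.66 (adjusted p = 0.0133; adjusted p = 0.652 with an estimated correlation). Adjusted over the list alone, 8 cytokine and chemokine genes, 6 macrophage genes of the Spp1 list and 3 inflammasome and IL-1 genes rose, against 0 mesothelial genes. Without the 3 libraries with thymus RNA those counts were 15, 12 and 4, with 16 cell cycle genes higher and 7 mesothelial genes lower. The cardiac muscle call ended without silica 1 (adjusted p = 0.0820), and the endothelial call without control 4, silica 1 or silica 7 (adjusted p = 0.0641, 0.0669 and 0.103).

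Plasma cell and immunoglobulin genes rested on 1 silica library. All 18 were higher in silica by a mean of 1.52 (adjusted p = 0.00222; adjusted p = 0.627 with an estimated correlation). The mean was -0.18 without silica 1. In that library the immunoglobulin heavy chain gene Ighg2c stood at 5916 CPM against 122 and 73.5 CPM in silica 2 and 7. Values of list genes that edgeR did not call were 6.36 ± 1.74 for the chemokine gene Cxcl3 (DESeq2 adjusted p = 0.00291), 2.48 ± 0.70 for the decoy receptor gene Il1r2, 2.96 ± 0.96 for Il1a and 1.78 ± 0.52 for Tnfaip2 (log2 scale, SE). Further values were 1.53 ± 0.53 for the NF-kB inhibitor gene Nfkbie, 2.15 ± 0.71 for the complement receptor gene C3ar1, 2.23 ± 0.76 for the mucin gene Muc5ac and -3.43 ± 1.09 for the mesothelial gene Bnc1. Limma-voom called these 8 genes.

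Fibrosis genes did not pass in silica against control with 15 libraries. The 28 collagen and matrix genes had a mean of 0.40, with 23 higher (adjusted p = 0.122; 0 adjusted over the list alone). The mean was -0.13 without silica 1 (adjusted p = 0.558), while the list passed without control 4, silica 2 or silica 7 (adjusted p = 0.0166, 0.0453 and 0.00326). It also passed without the 3 libraries with thymus RNA (0.36, adjusted p = 0.0335; adjusted p = 0.638 with an estimated correlation), and there with the gene length offset (0.44, adjusted p = 0.00731). The 17 genes of the TGF-beta response had a mean of -0.024, although camera set the list above other genes (adjusted p = 0.943). Of the 12 genes reported in any case, the cytokine gene Tnf (2.04 ± 0.63) and Ccl2 (3.15 ± 1.01) rose when adjusted over the list alone (adjusted p = 0.0440 for both) and not over all genes in the 15-library edgeR fit. The matrix genes stood at 0.69 ± 0.90 for Col1a1, 1.36 ± 0.91 for Col3a1, 0.98 ± 0.89 for Fn1, 0.12 ± 0.69 for Acta2 and 1.04 ± 0.99 for Timp1, and Col1a1 and Fn1 changed sign without silica 1 (-0.068 and -0.42). Spp1, which encodes osteopontin, stood at 2.83 ± 1.19, Il1b at 1.63 ± 0.91, Nlrp3 at 1.98 ± 1.11, Il6 at 1.29 ± 1.05 and Tgfb1 at 0.19 ± 0.40. Simulated genes changed 4-fold were called in 8% of cases with these 15 libraries and those changed 16-fold in 70%.

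The comparison of silica_DMSO with silica asks what DMSO did in lungs given silica, the question of the series title. With all libraries, thymocyte, T cell and cell cycle genes were higher in silica_DMSO, and lung epithelial, fibroblast, collagen and Spp1 macrophage genes were lower, while 2 of the 4 silica_DMSO libraries held thymus RNA. The 9 thymocyte genes rose by 7.84 (adjusted p = 7.43e-05), the 22 T and NK cell genes by 2.57 (adjusted p = 5.81e-06) and the 21 cell cycle genes by 2.04 (adjusted p = 2.35e-06), each with adjusted p = 0.541 with an estimated correlation. Alveolar type 2 genes fell by 0.78 (adjusted p = 5.78e-06), alveolar type 1 genes fell by 0.85 (adjusted p = 7.73e-06), and fibroblast genes fell by 0.78 (adjusted p = 7.24e-06). The 28 collagen and matrix genes fell by 0.71 (adjusted p = 1.74e-05) and the 20 lipid-handling and Spp1 macrophage genes fell by 0.58 (adjusted p = 0.000417), and for these 5 lists too it was adjusted p = 0.541 with an estimated correlation. In log2 CPM, which camera tests, the gap was wider for the alveolar type 2 list. Its mean stood at 9.33, 4.91, 9.46 and 2.96 in silica_DMSO 2, 4, 5 and 6, against 9.13 to 9.44 in silica. TGF-beta response genes fell by 0.57 (adjusted p = 0.000362; adjusted p = 0.541 with an estimated correlation). Inflammasome and IL-1 genes fell by 0.24 (adjusted p = 0.0390; adjusted p = 0.541 with an estimated correlation), a call that ended without silica 7, silica_DMSO 4 or silica_DMSO 6 (adjusted p = 0.0861, 0.0998 and 0.0572).

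Without the libraries labelled silica_DMSO 4, silica_DMSO 6 and DMSO 7, none of the lists above passed, and the thymocyte genes no longer met the filter on low counts. The collagen and matrix mean was then -0.31 (adjusted p = 0.211), the Spp1 macrophage mean -0.071 with a median of 0.13 (adjusted p = 0.431), and the alveolar type 2 mean 0.14 (adjusted p = 0.536). The TGF-beta mean was -0.011 (adjusted p = 0.909), the fibroblast mean 0.092 (adjusted p = 0.678), the cell cycle mean -0.12 (adjusted p = 0.739) and the T and NK cell mean 0.34 (adjusted p = 0.289). Cytokines and chemokines did not pass with 15 libraries (mean 0.081, while camera set the list below other genes, adjusted p = 0.122) or with 12 (0.56, adjusted p = 0.211), but were called lower without silica 2 or silica_DMSO 5 (adjusted p = 0.0324 and 0.00497), with the gene length offset (-0.20, adjusted p = 0.00476) and with the replicate block (-1.04, adjusted p = 0.00131). With 12 libraries 6 lists passed. The 24 interferon response genes rose by 0.70 (adjusted p = 1.76e-06; adjusted p = 0.955 with an estimated correlation), and the 9 mesothelial genes by 2.07 (adjusted p = 7.24e-08; adjusted p = 0.639 with an estimated correlation). Skeletal muscle genes rose by 1.16, liver genes by 1.62 and erythroid genes by 1.85 (adjusted p = 0.0392, 0.00189 and 0.000237; adjusted p between 0.955 and 0.967 with an estimated correlation). The 14 B cell genes fell by 1.00 (adjusted p = 3.45e-05; adjusted p = 0.955 with an estimated correlation). The mesothelial genes did not pass with 15 libraries (1.27, adjusted p = 0.336) and did without silica_DMSO 4 or 6 (adjusted p = 0.0282 and 0.00714). The interferon genes also rose with 15 libraries (0.54, adjusted p = 0.00164; adjusted p = 0.541 with an estimated correlation), which ended without silica 7 (adjusted p = 0.0919). The B cell value with 15 libraries, -0.81 (adjusted p = 0.0160), was -0.052 without silica 1, and the call also ended without silica_DMSO 2 or 5 (adjusted p = 0.145 and 0.151).

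EdgeR called no gene between silica_DMSO and silica. With 15 libraries the count was 0 (1056 at an unadjusted p under 0.05; DESeq2 70; limma-voom with quality weights 12275), and without the 3 libraries 0 (342 at an unadjusted p under 0.05). The genes of smallest p were Mfsd7a, of a family of membrane transporters, at -3.20 ± 0.76, Csf2ra, a receptor subunit for GM-CSF, at -1.87 ± 0.46, and Socs3, a brake on cytokine signalling, at -1.29 ± 0.33, each with adjusted p = 0.708. Fibrosis and inflammation genes reported in any case stood at -1.69 ± 0.90 for Col1a1, -0.98 ± 0.90 for Col3a1, -1.40 ± 0.90 for Fn1, -1.30 ± 0.69 for Acta2, and -0.27 ± 0.99 for Timp1. Values were -0.88 ± 1.15 for Spp1, -0.91 ± 0.62 for Tnf, -0.70 ± 0.90 for Il1b, -0.62 ± 1.06 for Il6, -0.54 ± 1.10 for Nlrp3, 0.031 ± 0.96 for Ccl2 and 0.10 ± 0.40 for Tgfb1 (all edgeR adjusted p at least 0.708, and at least 0.498 adjusted over the list alone).

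Of these, Spp1, Il1b, Il6, Nlrp3 and Timp1 turned positive without the 3 libraries (0.10, 0.18, 0.16, 0.36 and 0.54), and Tgfb1 turned to -0.54. Macrophage genes that edgeR did not call over all genes were Cd68 at -1.22 ± 0.45 and the phospholipase gene Pla2g7 at -2.15 ± 0.56. Both fell when adjusted over the 20 genes of their list alone. This was with all 15 libraries, and the list did not pass without the 3 libraries. The T cell receptor complex genes Cd3d and Cd3g stood at 3.94 ± 1.16 and 3.62 ± 1.15, Trbc2 at 5.43 ± 1.76 and Cd8b1 at 6.46 ± 2.11. The glutathione synthesis gene Gclc stood at -1.28 ± 0.46, the malic enzyme gene Me1 at -0.93 ± 0.38 and the arginine transporter gene Slc7a2 at -1.74 ± 0.70. The cathepsin gene Ctsl stood at 1.40 ± 0.53, the helicase gene Mcm2 at 2.08 ± 0.83 and the muscle light chain gene Mylpf at 3.10 ± 0.83. On all 15 libraries limma-voom with quality weights called 11 of the 12 genes lower and Tgfb1 higher (0.48, adjusted p = 0.0186), and none without the 3 libraries. Among the 11 were Spp1, Il1b and Nlrp3 (-5.14, -3.99 and -2.73, adjusted p = 7.61e-07, 1.90e-06 and 2.02e-05). The matrix genes were Col1a1, Col3a1, Acta2, Fn1 and Timp1 (-3.23, -3.06, -2.38, -2.21 and -2.17, adjusted p = 1.33e-05, 9.36e-06, 2.30e-05, 0.000199 and 0.000134). Cd3g turned to -0.043 without the 3 libraries and with a gene length offset. Means of Dntt were 735 normalised CPM in silica_DMSO and 0.236 in silica, of Ptcra 8.47 and 0.0156 normalised CPM, and of the myosin gene Myh4 0.653 and 0.0173 normalised CPM.

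The comparison of DMSO with control gives the effect of DMSO without silica. At the preset correlation, camera called goblet cell and mucus genes higher in DMSO, and endothelial, cardiac muscle and smooth muscle genes lower. None of these lists passed with an estimated correlation, and the goblet rise lay in DMSO 1 and DMSO 4. The 12 goblet and mucus genes rose by a mean of 3.04 (adjusted p = 0.00125; adjusted p = 0.700 with an estimated correlation). They rose by 3.14 without the 3 libraries with thymus RNA (adjusted p = 3.08e-06; adjusted p = 0.463 with an estimated correlation), where 10 of the 12 rose adjusted over the list alone. The mean log2 CPM of this list was 4.18 in DMSO 1 and 5.93 in DMSO 4, 2 libraries with an excess of short genes. It was 2.14 in DMSO 6 and 1.28 in DMSO 7, against 1.30 to 2.51 in the controls. Without DMSO 4 the list's mean was 1.62 and the call ended (adjusted p = 0.0516). The genes Clca1, Agr2 and Itln1, all products of mucous cells, stood at 6.20 ± 1.25, 5.55 ± 1.66 and 7.05 ± 2.14. EdgeR did not call them over all genes, and DESeq2 did (adjusted p = 9.22e-07, 0.00304 and 0.00194).

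Collagen and matrix genes fell by 0.52 and TGF-beta response genes fell by 0.64 in DMSO against control (adjusted p = 0.00125 and 0.000212; adjusted p = 0.700 for both with an estimated correlation). With 12 libraries they fell by 0.46 and 0.53 (adjusted p = 0.0102 and 0.00173; adjusted p = 0.520 and 0.463 with an estimated correlation), but not with the gene length offset as well (adjusted p = 0.400 and 0.0843). The collagen call also ended without DMSO 7 (adjusted p = 0.0532).

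Ciliated and club cell genes did not pass with 15 libraries (means 0.94 and 1.43, adjusted p = 0.679 and 0.324), and rose by 1.28 and 1.78 with 12 (adjusted p = 0.00173 and 0.00120; adjusted p = 0.463 with an estimated correlation for both). Both passed without DMSO 7 (adjusted p = 0.0253 and 0.0122), and the means were 0.047 and 0.52 without DMSO 4, a library with an excess of short genes (adjusted p = 0.376 and 0.989). Endothelial genes fell by 0.94 (adjusted p = 0.000212), cardiac muscle genes fell by 1.41 (adjusted p = 5.62e-05) and smooth muscle genes fell by 0.79 (adjusted p = 0.000212), each with adjusted p = 0.700 with an estimated correlation. Endothelial levels ranged lower, with overlap, in the 5 libraries with an excess of short genes, DMSO 1 and DMSO 4 among them (mean log2 CPM 4.68 to 6.65, against 5.93 to 7.11 in the other 7), and control 4 stood highest (7.11). With 12 libraries the endothelial, cardiac and smooth muscle lists fell by 0.76, 1.25 and 0.63 (adjusted p = 0.000342, 0.000342 and 0.0202; adjusted p = 0.463, 0.463 and 0.520 with an estimated correlation). Cytokines and chemokines rose by 1.06 (adjusted p = 0.0129; adjusted p = 0.709 with an estimated correlation), but not without DMSO 4 (0.20, adjusted p = 0.596) or control 1 (adjusted p = 0.0591), or with the gene length offset (0.58, adjusted p = 0.248). With 12 libraries they rose by 1.25 (adjusted p = 0.000342; adjusted p = 0.463 with an estimated correlation), and the offset kept that call (adjusted p = 0.0332). Thymocyte genes rose by 7.52 (adjusted p = 0.0177; adjusted p = 0.709 with an estimated correlation; adjusted p = 0.0636 without control 1). That rise rested on DMSO 7, where the mean log2 CPM of the list was 8.39, while the next DMSO library stood at 0.473. Cell cycle genes rose by 2.52 (adjusted p = 1.08e-05; adjusted p = 0.700 with an estimated correlation), a call that ended without DMSO 7 (0.43, adjusted p = 0.132) and held with 12 libraries (0.41, adjusted p = 0.00474; adjusted p = 0.520 with an estimated correlation). EdgeR called 0 genes with 15 libraries (1275 at an unadjusted p under 0.05; DESeq2 71; limma-voom with quality weights 6963) and 0 with 12 (1519 at an unadjusted p under 0.05).

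Among the DMSO genes that edgeR did not call, the chemokine genes Cxcl9 and Cxcl10 stood at 3.77 ± 0.88 and 1.63 ± 0.54, and the lactoferrin gene Ltf at 4.12 ± 1.31. The nucleic acid sensor gene Zbp1 stood at 1.61 ± 0.50, the mitotic kinase gene Bub1 at 3.04 ± 0.96, the cardiac troponin gene Tnnt2 at -2.32 ± 0.77 and the clock gene Per1 at -1.40 ± 0.43 (edgeR adjusted p = 0.649 for each of these 7).

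The silica_DMSO group was also compared with DMSO alone and with control, which gives the effect of silica in lungs given DMSO and that of the treatments together. Against control at the preset correlation, camera called cytokine and chemokine, interferon, Spp1 macrophage and cell cycle genes higher in silica_DMSO, and circadian clock genes lower. None of these lists passed with an estimated correlation, and 2 of 35 groupings, the real one included, gave as many lists. With 12 libraries only silica_DMSO 2 and silica_DMSO 5 stand for the group, the latter with an excess of short genes. Cytokines and chemokines rose by 2.06 (adjusted p = 4.82e-05; adjusted p = 0.427 with an estimated correlation), with 12 genes adjusted over the list alone, and by 2.51 without the 3 libraries with thymus RNA (adjusted p = 1.02e-16; adjusted p = 0.113 with an estimated correlation), with 18. Spp1 macrophage genes rose by 1.32 (adjusted p = 0.0107; adjusted p = 0.533 with an estimated correlation) and by 1.80 with 12 libraries (adjusted p = 2.15e-13; adjusted p = 0.113 with an estimated correlation). Interferon response genes rose by 1.22 (adjusted p = 5.90e-08; adjusted p = 0.427 with an estimated correlation) and by 1.35 with 12 libraries (adjusted p = 2.89e-14; adjusted p = 0.170 with an estimated correlation). Cell cycle genes rose by 3.30 (adjusted p = 2.80e-11; adjusted p = 0.427 with an estimated correlation) and by 1.10 with 12 libraries (adjusted p = 1.17e-13; adjusted p = 0.169 with an estimated correlation). Circadian clock genes fell by 0.85 (adjusted p = 4.71e-05; adjusted p = 0.427 with an estimated correlation) and by 0.71 with 12 libraries (adjusted p = 0.000255; adjusted p = 0.478 with an estimated correlation). Collagen and matrix genes fell by 0.30 (adjusted p = 0.00594; adjusted p = 0.547 with an estimated correlation), and the mean was 0.057 with 12 libraries (adjusted p = 0.848). TGF-beta response genes fell by 0.59 (adjusted p = 0.00410; adjusted p = 0.505 with an estimated correlation), with a mean of -0.067 with 12 libraries (adjusted p = 0.921). The Spp1 macrophage call ended without silica_DMSO 2 or 5 (adjusted p = 0.0877 and 0.281), and the collagen call without silica_DMSO 6 (adjusted p = 0.0791).

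**Figure D4:**
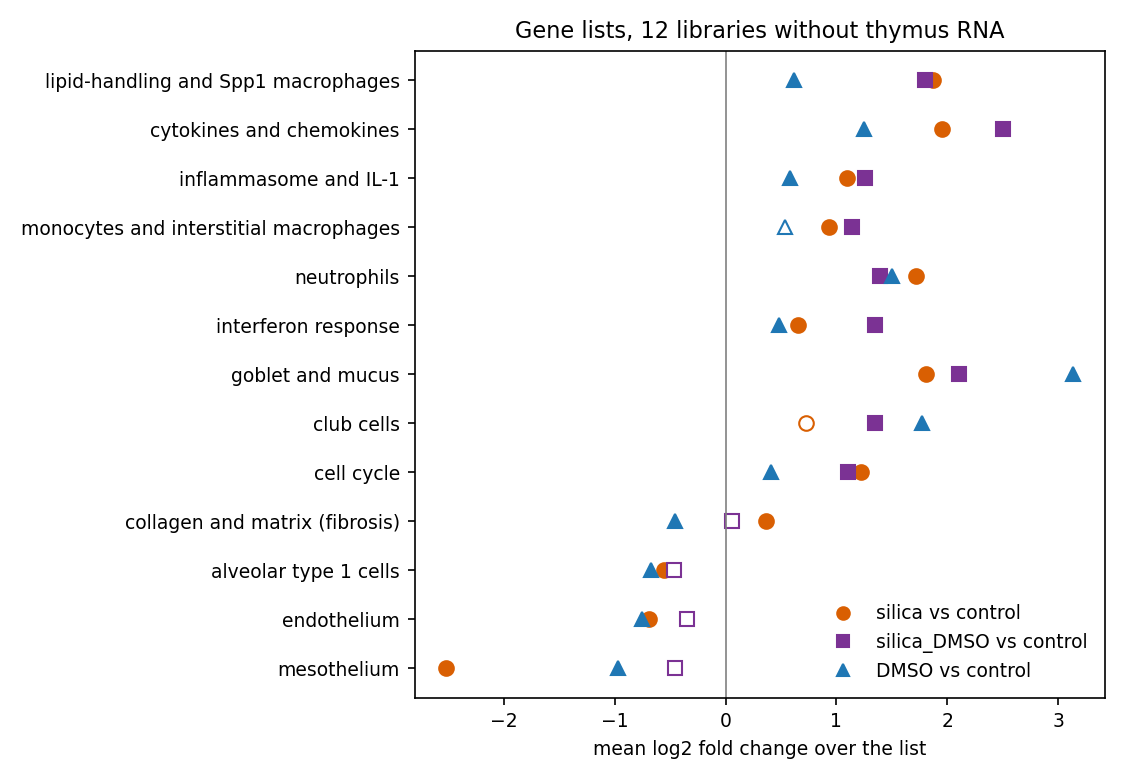
Mean log2 fold change against control (horizontal axis) of 13 gene lists (vertical axis) with the 12 libraries without thymus RNA, for silica, silica_DMSO and DMSO, with filled symbols where the limma camera adjusted p at a preset correlation is under 0.05. Spp1 macrophage genes lie at 1.87 in silica and 1.80 in silica_DMSO, and mesothelial genes at -2.52 in silica.

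Mmp12 passed in silica_DMSO against control without the 3 libraries, at 4.51 ± 0.43 (edgeR adjusted p = 0.00612), from 7.53 ± 1.86 to 172 ± 94.8 normalised CPM (SD, n = 4 and 2). With 15 libraries edgeR called 0 genes against control (3075 at an unadjusted p under 0.05; DESeq2 946; limma-voom with quality weights 12229), and 1956 without silica_DMSO 2, when 2 of the 3 libraries left in the group held thymus RNA. Genes of smallest p, all with edgeR adjusted p = 0.218, were Cxcl10 at 3.01 ± 0.57, the chemokine gene Ccl22 at 2.28 ± 0.53, Nfkbie at 2.22 ± 0.51, and the activation marker gene Cd83 at 2.04 ± 0.40. With the same adjusted p, the interferon-induced genes Zbp1 and Isg15 stood at 2.37 ± 0.51 and 3.01 ± 0.75, the mitosis genes Birc5, Cdk1 and Aurka at 4.03 ± 1.02, 3.85 ± 0.99 and 3.74 ± 0.97, and the clock repressor genes Ciart and Nr1d1 at -2.78 ± 0.59 and -2.57 ± 0.61.

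Against DMSO at the preset correlation, camera called interferon, NF-kB and cytokine genes higher in silica_DMSO, and none of these lists passed with an estimated correlation. Interferon response genes rose by 0.76 (adjusted p = 6.34e-12; adjusted p = 0.338 with an estimated correlation), and NF-kB targets by 0.51 (adjusted p = 6.29e-05; adjusted p = 0.0650 with an estimated correlation). Cytokines and chemokines rose by 1.00 (adjusted p = 0.000129; adjusted p = 0.457 with an estimated correlation) and Spp1 macrophage genes by 0.90 (adjusted p = 0.00146; adjusted p = 0.483 with an estimated correlation). Cell cycle genes rose by 0.78 (adjusted p = 2.85e-09; adjusted p = 0.457 with an estimated correlation). Without the 3 libraries with thymus RNA the interferon, cytokine and Spp1 macrophage means were 0.87, 1.25 and 1.18 (adjusted p = 6.57e-13, 2.82e-11 and 2.82e-11; adjusted p = 0.209, 0.209 and 0.191 with an estimated correlation). The NF-kB and cell cycle means were then 0.46 and 0.69 (adjusted p = 0.00186 and 5.14e-10; adjusted p = 0.191 and 0.215 with an estimated correlation). Ciliated cell genes fell by 0.94 (adjusted p = 1.20e-05; adjusted p = 0.457 with an estimated correlation), and alveolar type 2 genes fell by 0.40 (adjusted p = 6.80e-06; adjusted p = 0.457 with an estimated correlation). Neither passed when those libraries were out (means -0.40 and 0.23). Collagen and matrix genes and TGF-beta response genes did not pass with 15 libraries (0.22 and 0.044, adjusted p = 0.433 and 0.669). They rose by 0.51 and 0.46 with 12 (adjusted p = 0.000511 and 0.000144; adjusted p = 0.603 and 0.276 with an estimated correlation). Without silica_DMSO 2 alone camera called the collagen list lower (-0.34, adjusted p = 0.0207), and without silica_DMSO 6 alone higher (0.50, adjusted p = 0.0308). The cytokine call ended without DMSO 7 or silica_DMSO 5 (adjusted p = 0.110 and 0.312), and the Spp1 macrophage call without DMSO 7, silica_DMSO 2 or silica_DMSO 5 (adjusted p = 0.299, 0.0562 and 0.501). Both calls also ended with the replicate block (-0.057 and -0.17).

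Against DMSO edgeR called no single gene. With 15 libraries the count was 0 (305 at an unadjusted p under 0.05; DESeq2 1; limma-voom with quality weights 12413), and with 12 libraries 0 (335 at an unadjusted p under 0.05). Mmp12 stood at 3.26 ± 1.00, the neutrophil chemokine gene Cxcl2 at 5.44 ± 1.87, and Ccl22 at 1.51 ± 0.52. The antiviral genes Stat2, Ifi44 and Rsad2 stood at 0.86 ± 0.29, 1.20 ± 0.41 and 1.14 ± 0.42. The B cell receptor gene Cd79a stood at -1.27 ± 0.48 (edgeR adjusted p = 0.998 for each of these 7). Without the 3 libraries with thymus RNA, Mmp12 stood at 3.90 ± 0.47, the smallest adjusted p there (edgeR adjusted p = 0.0663).

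The interaction asks whether the effect of silica differed with DMSO. The mean difference over a list was negative for goblet and mucus genes (-3.00, adjusted p = 8.43e-07; adjusted p = 0.568 with an estimated correlation) and neutrophil genes (-1.75, adjusted p = 1.77e-05; adjusted p = 0.568 with an estimated correlation). It was also negative for Spp1 macrophage genes (-1.01, adjusted p = 3.17e-06; adjusted p = 0.592 with an estimated correlation), cytokines and chemokines (-0.98, adjusted p = 7.53e-05; adjusted p = 0.592 with an estimated correlation) and plasma cell genes (-2.61, adjusted p = 0.00181; adjusted p = 0.598 with an estimated correlation). It was positive for mesothelial genes (2.36, adjusted p = 1.77e-05; adjusted p = 0.592 with an estimated correlation). Without the 3 libraries with thymus RNA the cytokine difference was -0.70 and the call ended (adjusted p = 0.0544). The goblet, neutrophil, Spp1 macrophage and plasma cell lists passed there, but not with an estimated correlation (adjusted p = 0.464, 0.526, 0.526 and 0.611), and the mesothelial difference was 3.04 (adjusted p = 2.73e-11; adjusted p = 0.262 with an estimated correlation). The plasma cell call ended without DMSO 4 or silica 1 (adjusted p = 0.227 and 0.628).

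For single genes the interaction test in edgeR called 0 with 15 libraries (297 at an unadjusted p under 0.05; DESeq2 12; limma-voom with quality weights 10824) and 0 with 12 (485 at an unadjusted p under 0.05). The immunoglobulin gene Ighg2c stood at -6.46 ± 2.30, the goblet cell gene Clca1 at -7.00 ± 1.58, Muc5ac at -3.73 ± 1.05, Cxcl9 at -5.24 ± 1.20, and Cd68 at -1.99 ± 0.62, all with adjusted p = 1.00. Across 17879 genes, which are not independent, the silica effect without DMSO and that with DMSO correlated at r = 0.0757 with a slope of 0.0692. These effects share no library. Simulated unchanged groups, with each gene drawn independently, gave r = -0.00116. Shifts shared across genes, as by thymus RNA or gene length, were not simulated, so the gap from that value cannot be read as an effect. Without the 3 libraries with thymus RNA the correlation of the silica effects was -0.0696.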

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

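Tests of thymus RNA, of the excess of short genes and of the silica-raised genes in silica_DMSO were chosen only after the result was seen, as were the splits of 7 libraries. The 12-library fits were too, although their splits were set before those were run.

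Of 129 sets of 4 libraries and measured quantities, 15 (11.6%) had a library far from the other 3, where chance gives about 1 in 20 (5%). In DMSO 7 these were the first principal component (138), the mean log2 CPM of the thymocyte list (8.39), Rag1 (3876 CPM), Cd8a (1480 CPM) and Spp1 (13.4 normalised CPM). In DMSO 4 they were Ighg2c (2361 CPM), Saa3 (126 CPM) and Ccl2 (7.96 normalised CPM). In silica_DMSO 5 they were the TMM factor (0.478) and Saa3 (403 CPM), and in silica_DMSO 2 Xist (13.1 CPM) and Col1a1 (165 normalised CPM). Among controls, control 4 stood apart in the endothelium list (7.11) and Fn1 (420 normalised CPM), and control 7 in Slc39a2 (1.76 CPM). The 3 silica libraries were too few for this test.

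By the interaction test at a preset correlation, the effect of silica differed with DMSO for 6 lists singled out: cytokines and chemokines (-0.98), lipid-handling and Spp1 macrophages (-1.01), neutrophils (-1.75), plasma cells and immunoglobulin (-2.61), goblet and mucus (-3.00) and mesothelium (2.36), none of which passed with an estimated correlation.

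In the libraries labelled DMSO 7, silica_DMSO 4 and silica_DMSO 6, thymocyte genes stood far above the other 12 libraries. Of 12 thymic epithelium genes, 11 were at least 10 times higher in each of the 3 than in any of the other 12, with a median ratio of 48.7, which argues against T lymphocytes gathered in the lung, since lymphocytes do not make Foxn1 or Psmb11. Of these 12 genes, 6 reach 1 CPM in the other 12 libraries and 3 are in another list. Silica followed by DMSO is argued against as well, since the lowest silica_DMSO library lay 0.25 below the highest control (-0.25, thymocyte list). Thymus tissue in these libraries may be the source, and whether by dissection or by a wrong label stays open.

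In control 1, DMSO 1, DMSO 4, silica 7 and silica_DMSO 5 short genes were in excess. Ribosomal protein genes alone do not account for it, since without them the weakest correlation with gene length among the 5 was -0.167. The treatments alone do not either, since the 5 libraries come from every group, control included. The smallest range within a group (0.626) exceeded the range of the group means (0.360). Means vary less than single libraries, so this comparison cannot exclude that the treatments had a part. A difference in RNA quality or in airway content of the piece stays open and was not tested.

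The 40 genes raised by silica in the 7-library fit lay above the controls in silica_DMSO 2 and 5, by a median of 2.71 on the log2 scale. Random sets matched on level and length reached at most 0.816 (permutation p = 0.0001, the smallest that 10000 sets can give). A silica response present after DMSO could explain this, but this test alone does not set silica apart, since DMSO 1 and DMSO 4 gave the same permutation p = 0.0001, while DMSO 6 gave permutation p = 0.875. Low controls in the choice of genes are argued against, since genes picked with 2 controls stood at least 2.33 above the 2 controls left out. A shift of single libraries without silica cannot be told apart for part of the genes, since DMSO 1 stood at 1.23 and DMSO 4 at 2.85, both with an excess of short genes. The silica libraries themselves stood at 2.88. Of the libraries without that excess, DMSO 6 stood at -0.068 and silica_DMSO 2 at 1.93, with 6 and 40 of the 40 genes above the highest control, but each is a single library. In both silica_DMSO libraries, 9 of the 40 exceeded all 7 lung libraries without silica, against 1.71% of all genes. The controls used to pick the 40 are among these 7, and the share of all genes is not matched on level or length. This contrast is therefore partly built in.

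All splits of the libraries into groups of the same sizes, or 100 for the interaction, were fitted, the real one included. For silica against control, 1 of 35 splits, the real one, gave as many lists as the real 23 with 15 libraries (highest other 21), 26 with 12 (25) and 26 with 7 (23). Likewise only the real 1 of 35 gave as many genes as the real 2 with 12 libraries (0) and 41 with 7 (0). For these counts the real grouping ranked first, at 1 in 35, the smallest share possible here. That is under 0.05, the limit set for chance, but no allowance was made for the number of split tests. Nor was any made for the 12-library fits, and the list tests and splits of 7 libraries, being chosen after the data were seen. With 15 libraries the real gene counts of 0 were met in 35 of 35 splits for silica against control and DMSO against control (highest other 0), silica_DMSO against silica (542), against DMSO (5178) and against control (580), and in 100 of 100 for the interaction (4597). A real count of 0 is met by every split, so these splits carry nothing on chance. The large counts point to a structure of the libraries beyond the groups. Against DMSO, counts of 2621, 5178, 4564, 3234 and 1266 came from the splits that put the 3 libraries with thymus RNA together. The other splits of that comparison gave at most 43 genes, so thymus RNA may be the structure there. For the large counts of the other comparisons the cause was not tested. List counts were met in 2 of 35 splits for silica_DMSO against silica (29, highest other 29) and against control (29, 29), 7 against DMSO (25, 31), 5 for DMSO against control (21, 25) and 11 of 100 for the interaction (25, 28), where chance cannot be excluded. For DMSO against control with 12 libraries the real count was again 0 genes, met by 35 of 35 splits of necessity. Of 35 splits 1, the real one, gave as many lists as the real 29 (highest other 25), under the limit of 0.05 but with the same allowances missing. With 15 libraries 5 of 35 splits met the real count, and no list passed with an estimated correlation. Chance is therefore not excluded for the DMSO lists.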

How the results depend on the processing

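Fits without the thymus libraries, with a gene length offset, or of 7 libraries with lists or a library left out were chosen after seeing the data. The cause of a change was not tested unless stated. Of 2539 fits of 116 results for named genes, 2286 kept direction and side of the threshold, 206 became significant and 47 reversed. Of 1088 for 62 named list results, 822 kept both, 198 lost the call, 22 gained it and 46 reversed. For lists this is the direction of camera against other genes, which can turn while the mean keeps its sign. Genes called were, for silica against control, 41 with 7 libraries, 39 (DESeq2), 1470 (voom with weights), without the thymus libraries 2, 8 with the length offset and 1334 by voom. They were also 1, 7, 1 and 3 without control 1, DMSO 4, silica_DMSO 5 or all 3, and 0 to 37 leaving out 1 library. By DESeq2 and voom they were 70 and 12275 for silica_DMSO against silica, 71 and 6963 for DMSO against control (8474 by voom without the thymus libraries), and 1 and 12413 against DMSO. They were 946 and 12229 for silica_DMSO against control, and 12 and 10824 for the interaction. For silica_DMSO against control they were 1 without the thymus libraries, 1 with the offset, 1, 1 and 2 without control 1, DMSO 4 or silica_DMSO 5, and 0 to 1956 leaving out 1 library. Voom gave silica_DMSO 4 and 6 weights of 4.59 and 1.45 and silica_DMSO 2 and 5 weights of 0.127 and 0.108, so its calls for silica_DMSO rest mostly on libraries with thymus RNA. It gave silica 2 a weight of 10.7 and silica 1 and 7 0.551 and 0.798, and DMSO 1 9.02 (13.1 without the thymus libraries) against 0.165 to 0.681 in the other DMSO libraries, so its other counts rest largely on 1 treated library. Its count fell to 0 without the thymus libraries in the 3 comparisons with silica_DMSO and the interaction. Lists called with an estimated correlation were 3 for silica against control (7 without the thymus libraries, 3 with 7 libraries) and 0 in the other 5 comparisons, with or without those libraries. Fry called 1 for silica against control (8 without the thymus libraries), 3 for silica_DMSO against control (5) and 0 elsewhere. For silica_DMSO against silica, 6 lists passed without the thymus libraries and 10 with the offset. The correlation of silica effects was -0.0696 without the thymus libraries and -0.0817 to 0.265 leaving out 1.

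Reversed for silica against control were Fn1 by voom (-0.22, -0.24 without the thymus libraries) and Acta2 by TPM (-0.10, -0.10) and with the replicate block (-0.049); the TGF-beta list mean was -0.18 with the block and -0.022 with 7 libraries. For silica_DMSO against silica, without the thymus libraries, Tgfb1 (-0.54), Spp1 (0.10), Il1b (0.18), Il6 (0.16), Nlrp3 (0.36), Timp1 (0.54), cell cycle (-0.12), alveolar type 2 (0.14) and type 1 (0.088), fibroblasts (0.092) reversed, as did the camera direction of cytokines (0.56, mean still positive), while the inflammasome mean turned positive (0.16). With the offset too, these were Col3a1 (0.37), Fn1 (0.038), Tgfb1 (-0.55), Il1b (0.14), Ccl2 (-0.053), Nlrp3 (0.20), Cd3g (-0.043), T and NK cells (0.041, in camera direction only), TGF-beta (0.16), cell cycle (-0.090), type 2 (0.047) and fibroblasts (0.13). By voom there, they were Col3a1 (0.43), Fn1 (0.79), Tgfb1 (-0.65), Spp1 (0.17), Tnf (0.0098), Il6 (0.16) and Timp1 (0.044). With all libraries Tgfb1 reversed by TPM (-0.17, -0.22) and Ccl2 without a filter (-0.024), with the block (-1.40), voom (-2.29), TPM (-0.99, -1.12) and the offset (-0.78). Against DMSO, Mmp12 reversed by voom (-1.02), Car3 by voom without the thymus libraries (0.065), and alveolar type 2 without them (0.23, 0.21 with the offset); collagen against control likewise (0.057, 0.27), and TGF-beta against control with both (0.16). Against DMSO the camera direction reversed there for collagen (0.51, 0.36 with the offset) and TGF-beta (0.46, 0.43). Leaving out 1 library, Col1a1 ran from -0.068 to 1.07, Fn1 -0.42 to 1.52, Acta2 -0.51 to 0.51, collagen -0.13 to 0.59, TGF-beta -0.22 to 0.10 and plasma cells -0.18 to 1.90 for silica against control. Tgfb1 ran from -0.10 to 0.34, Ccl2 -1.43 to 0.42, Timp1 -1.73 to 0.19 and mesothelium 0.60 to 1.61 for silica_DMSO against silica, collagen -0.34 to 0.50 and TGF-beta -0.39 to 0.31 against DMSO, and ciliated 0.047 to 1.30 and club cells 0.52 to 1.80 for DMSO against control. No pairing of libraries by the label's number was seen. Of 13 pairs with the same number 4 correlated above 0.1 (across genes, deviations from the mean), with r from -0.487 to 0.266. These deviations also carry thymus RNA and the shift with gene length, so this check cannot exclude pairing. The replicate block gave 0 genes by edgeR in each comparison, as the fit without it did, which carries nothing on pairing. The block ended the calls of Spp1 macrophages (-0.17) and cytokines (-0.057) against DMSO, Spp1 macrophages for silica_DMSO against control (0.38), interferon for silica_DMSO against silica (0.036) and thymocytes for DMSO against control (4.36). With it cytokines were lower for silica_DMSO against silica (-1.04), and ciliated (1.53) and club cells (2.06) higher for DMSO against control.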

Other observations

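Xist, the RNA that silences an X chromosome in females, stood at 13.1 CPM in silica_DMSO 2 and 9.70 CPM in silica 7. Elsewhere it reached at most 0.563 CPM. The Y-linked gene Ddx3y was present in every library (16.4 to 128 CPM), with 59.3 CPM in silica_DMSO 2 and 35.5 CPM in silica 7. The transducin gene Gnat1 was at most at 0.375 CPM in every library and the arrestin gene Sag at most at 1.58 CPM, while the crystallin genes Cryaa and Cryab reached 6.08 and 303 CPM.

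Ribosomal protein genes took 7.56% to 23.3% of counts in the 5 libraries with an excess of short genes and 2.84% to 4.54% in the other 7 without thymus RNA. Prss16, a protease of thymic cortex, lay between 367 and 716 CPM in the 3 libraries with thymus RNA and at most at 1.06 CPM in the other 12.

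Across genes, which are not independent, silica against control and DMSO against control correlated at r = 0.589. Simulated unchanged groups sharing the controls gave 0.462. Silica against control and silica_DMSO against silica correlated at r = -0.0642, where simulated unchanged groups sharing the silica libraries gave -0.572. The simulation drew each gene independently, without the shifts that thymus RNA or gene length bring across genes. The gaps from it therefore cannot be read as effects.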
